A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

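Total RNA from a Saccharomyces cerevisiae strain lacking GCR1 and from its wild type was compared on 3 Agilent oligonucleotide arrays, 1 for each time point. Per the labels, channel 1 carried Cy5 and channel 2 Cy3, and cRNA was made with a low-input linear amplification kit from Agilent. The labels put 3% pyruvate in the medium before glucose (0 min) and give samples at 20 and 60 min after glucose was added. No dye-swapped array was analysed here, so a dye bias of a single probe cannot be separated from a strain difference on 1 array. Such a bias, if constant, cancels in a difference between time points.

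The deposited value table held a log2 ratio of the 2 channels for each of 10807 probes on each array. The base of the logarithm was read from the values, because the gaps between tied values were those of ratios of small whole numbers on a log2 scale. The authors' scanner software, background correction, normalisation and filters are not given in the sources used here. The columns were not centred on 0, with medians over all probes of 0.02 at 0 min, -0.15 at 20 min and -0.08 at 60 min. Which strain is the numerator of the ratio is not stated in the labels. Array intensities were not analysed here, and the number of arrays limits the precision.

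Probes were named through the platform annotation, in which 9202 probes had 1 gene symbol, 0 had several and 1605 had none. Of the named probes, 9194 matched a gene ID in NCBI RefSeq's R64 annotation of the reference strain, and 0 symbols changed by that match. The genome build of the probe design is not given in the sources used here, so no coordinates were used. Values of different probes of a gene were averaged, which gave 5598 genes, of which 2010 had 1 probe, 3576 had 2 and 12 had 3 or 4. A value on all 3 arrays was present for 5593 genes. Probes of near-identical genes, such as TDH2 and TDH3, ENO1 and ENO2, HXT6 and HXT7 or paired ribosomal protein genes, can bind each other's cRNA, so the split between such partners is uncertain.

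With 1 array per time point there was no test between the strains at a single time, no p-value and no standard deviation between replicates, and a strain effect common to the 3 arrays was not tested. Genes were counted where the ratio was at least 2-fold on either side, a log2 value of 1.0 or more in size. The technical error was taken from genes with 2 probes. For each gene list, the median on an array was set against the medians of 10000 random lists of the same size drawn from the genes measured on that array. A list was called outside that range when its median lay below the 2.5th or above the 97.5th percentile. The random lists were not matched on expression, and the percentiles describe these 3 arrays only. Differences between time points were differences of log2 ratios per gene, and the differences 20 minus 0 min and 60 minus 0 min share the 0 min array. Correlations were computed over genes, which are not independent replicates. Intervals over list members came from 2000 bootstrap draws at a confidence of 95%, and describe the spread between members.

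Gene lists, thresholds, the rule for named genes and most alternatives were fixed before the data were examined. There were 33 lists, covering carbon metabolism, respiration, ribosomes and translation, stress, nutrient pathways, the cell cycle, mating type, laboratory marker genes and sporulation, and 32 of them had members measured. Transcripts of the mitochondrial genome were the list with 0 members measured and are not analysed here. Some other list members are not reported here. Genes named per array were GCR1, the 8 highest and 8 lowest genes, all members of the glycolysis list, and up to 4 members of largest size from each list outside its random range. For each difference between time points, the 8 highest and 8 lowest genes were named. Other genes named in the text were chosen after their values were seen.

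Alternatives were a threshold of 1.5-fold or 3-fold, centring each array on its median, scaling the arrays to equal spread, the median over probes of a gene, only genes valued on all 3 arrays, values of exactly 0 left out, the mean over list members, paralog pairs counted once, Spearman correlation, and correlations without genes beyond 2-fold or without list members. After the data were seen, a further alternative left out genes of low signal. A gene was taken as low signal on an array when every probe was missing or lay within 0.001 of the log2 ratio of 2 whole numbers of at most 8, after the offset of that array. Ratios beyond 8-fold after that offset could not be flagged, and a value can match this rule by coincidence.

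The calculations were checked on simulated data for 5598 genes, in which spiked 4-fold genes were recovered at 100.0% on each simulated array. Spiked 2-fold genes, which lie on the threshold, were recovered at 48.0% for 0 min, 57.5% for 20 min and 49.5% for 60 min. False calls numbered 0. The design of the simulation fixed both this and the 4-fold recovery, because its unchanged genes were drawn from values under 1.5-fold. The real arrays spread more widely, with a standard deviation over genes of 1.17 at 20 min and 1.10 at 60 min. The simulation therefore checked only that the counting ran as written. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.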

Results

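Transcript levels in budding yeast lacking GCR1, which encodes an activator of glycolytic gene transcription, were compared with those of the wild type before and after glucose was added to cells growing on 3% pyruvate. RNA of both strains was hybridised together on 1 array at 0 min, just before the addition, and on 1 array each at 20 and 60 min after it. A log2 ratio of the strains was obtained for 5596 genes at 0 min, 5597 at 20 min and 5596 at 60 min. The median gene stood at 0.07, -0.08 and 0.05. There was 1 array per time point, so no difference has a replicate check, and the error that could be measured was that between 2 probes of a gene. Probe pairs differed by a median of 0.11 on each array, and 95% of them differed by less than 0.41 at 0 min, 0.48 at 20 min and 0.38 at 60 min, all below the log2 value of 1.0 that marks 2-fold. Both probes of a pair read the same cRNA on the same array. Their difference therefore leaves out variation between cultures, RNA preparations, labelling and arrays, and cannot show that a 2-fold value exceeds it.

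GCR1 itself (YPL075W), the gene inactivated in the mutant, had positive ratios on all 3 arrays, 0.97 at 0 min, 0.91 at 20 min and 1.51 at 60 min. The labels do not say which strain is the numerator. The array titles name the null mutant and the study design names it first, so mutant over wild type is the likely direction, but a positive GCR1 ratio goes against it if its 2 probes lie in the deleted part. Their position is not given in the sources used here, and probes outside that part would check nothing. Ratios are therefore given as positive or negative, with the positive side being that of GCR1. GCR1 and the factors that act with it at promoters had a list median of 0.29, -0.26 and -0.36 over 6 genes, inside the random range on each array. Among them GCR2, its binding partner, had 0.35, 0.12 and 0.21. TYE7, a helix-loop-helix activator of glycolytic genes, had 0.23, 3.15 and 2.82, and ABF1, a general regulatory factor, had 0.41, -1.70 and -1.25.

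In the values as deposited, the strains differed by 2-fold in few genes on pyruvate and in many after glucose. At 0 min 61 genes were at least 2-fold positive and 126 at least 2-fold negative, 3.34% of the genes measured. At 20 min the counts were 958 and 925 (33.6%), and at 60 min 906 and 759 (29.8%). Leaving out genes of low signal took the negative count at 0 min to 29, and the positive count stayed at 61. Scaling the arrays to equal spread, which removes differences in spread by construction, ended this contrast, with 471 positive and 672 negative genes at 0 min, 718 and 458 at 20 min and 595 and 543 at 60 min. Of genes beyond 2-fold, 575 were positive and 412 negative at both 20 and 60 min, where independent lists would share 155.1 and 125.3, and 17 were on opposite sides. The arrays at 0 and 20 min shared 43 positive genes, against 10.4 for independent lists, and 63 negative genes, against 20.6. With genes of low signal left out, they shared 43 positive genes, against 11.2, and 12 negative genes, against 3.5. The correlation over genes was 0.739 between 20 and 60 min, 0.304 between 0 and 20 min and 0.331 between 0 and 60 min. All 3 arrays compared the same strains, and no dye-swapped array was analysed. A constant probe or dye bias, or a fixed strain difference, would also raise the sharing and the correlations, and was not separated.

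**Figure D1:**
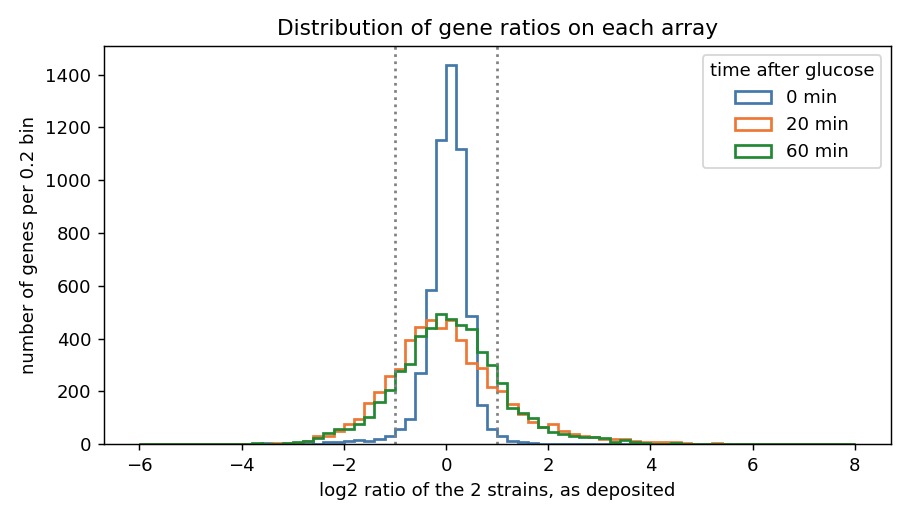
Number of genes (vertical axis, per bin of 0.2) by log2 ratio of the 2 strains as deposited (horizontal axis) on the arrays at 0, 20 and 60 min, 1 array each, with dotted lines at 2-fold. The 0 min distribution is narrow, with 3.34% of genes beyond 2-fold, against 33.6% at 20 min and 29.8% at 60 min.

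On pyruvate, before glucose, the glycolytic enzymes stood apart from all other groups. All 13 members of the glycolysis list were negative and 10 of them at least 2-fold, with a list median of -3.43 (10.8-fold) against a random range of -0.14 to 0.27. GPM1, phosphoglycerate mutase, was the lowest gene on the array at -5.55, a 46.7-fold difference. The enolases ENO2 and ENO1 had -4.73 and -3.86, the glyceraldehyde-3-phosphate dehydrogenases TDH3 and TDH2 -3.83 and -3.45, triosephosphate isomerase TPI1 -3.56 and pyruvate kinase CDC19 -3.43. Phosphoglycerate kinase PGK1 had -3.0, phosphoglucose isomerase PGI1 -3.17 and aldolase FBA1 -2.96. The phosphofructokinase subunits PFK1 and PFK2, at -0.62 and -0.29, and the third glyceraldehyde-3-phosphate dehydrogenase TDH1, at -0.94, were within 2-fold. Of the fermentation genes, the main alcohol dehydrogenase ADH1 had -2.61 and ADH5, a minor form, 2.31, so that the list median of -0.33 covered 1 gene beyond 2-fold on each side.

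Other groups at 0 min lay much closer to 0. Genes for growth on non-fermentable carbon had a median of 0.48, with 3 of 20 at least 2-fold positive, namely the acetate transporter ADY2 (1.83), alcohol dehydrogenase ADH2 (1.17) and mitochondrial aldehyde dehydrogenase ALD4 (1.13). Storage carbohydrate genes had a median of 0.52 with 0 of 20 beyond 2-fold, and NTH2, a trehalase, was highest at 0.89. General stress genes had a median of 0.45 with 2 of 36 beyond 2-fold, GCY1 (1.26) and ALD3 (1.18). Negative medians outside the random range were found for mating and pheromone genes (-0.48, 17 of 19 below 0), cytosolic ribosomal proteins (-0.30, 125 of 135 below 0), mitochondrial ribosomal proteins (-0.26, 59 of 67 below 0) and nuclear genes of oxidative phosphorylation (-0.15, 28 of 34 below 0), and the mating gene FUS1, at low signal (-1.33), was the 1 member of these lists to reach 2-fold. Scaling the arrays to equal spread took these medians to -1.34, -0.91, -0.79 and -0.53. Small positive medians outside the range were those of amino acid biosynthesis (0.29), purine biosynthesis (0.29), G1/S genes (0.30) and histones (0.35).

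The highest genes at 0 min belonged to different pathways. GCN4 (YEL009C), the activator of amino acid biosynthesis genes, was 202-fold positive at 7.66, and its 2 probes gave 7.59 and 7.73. IMD2, an IMP dehydrogenase, had 3.32, the uracil synthesis gene and common marker URA3 had 2.83, the polyamine exporter TPO2 2.26, SPG4 1.70 and the weak acid transporter PDR12 1.66. PET122, a translational activator of a mitochondrial mRNA, was among the 8 lowest at -4.01.

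After glucose most glycolytic genes were nearer to 0, but not alike. TDH1 at 20 and 60 min, and PFK1 and PFK2 at 60 min, were farther from 0 than at 0 min. At 20 min 5 of 13 were at least 2-fold negative and 2 at least 2-fold positive, with a median of -0.29, and at 60 min the same numbers held with a median of -0.47. Both medians were inside the random range. Negative beyond 2-fold at 20 min were GPM1 (-3.75), CDC19 (-2.5), PGI1 (-2.05), ENO2 (-1.80) and TPI1 (-1.5), while TDH1 (3.53) and ENO1 (1.12) were positive. At 60 min GPM1 had -2.25, CDC19 -2.33, ENO2 -1.91, PGI1 -1.65 and PFK1 -1.02, and TDH1 (4.47) and TDH2 (1.24) were positive. The single CDC19 probe matched the low-signal rule at 60 min. On that array 9.5% of named probes matched it, against a chance share of 2.2% over all probes, so a coincidental match is possible. The remaining values at 20 and 60 min were 0.41 at 20 min for TDH2, -0.24 and 0.10 for TDH3, -0.86 and -0.29 for PGK1, -0.28 and 0.35 for FBA1, 0.19 at 20 min for PFK1, -0.08 and -0.71 for PFK2, -0.47 at 60 min for TPI1 and 0.89 at 60 min for ENO1. TDH1, TDH2 and TDH3, and also ENO1 and ENO2, are near-identical in sequence, so their separate values are uncertain.

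**Figure D2:**
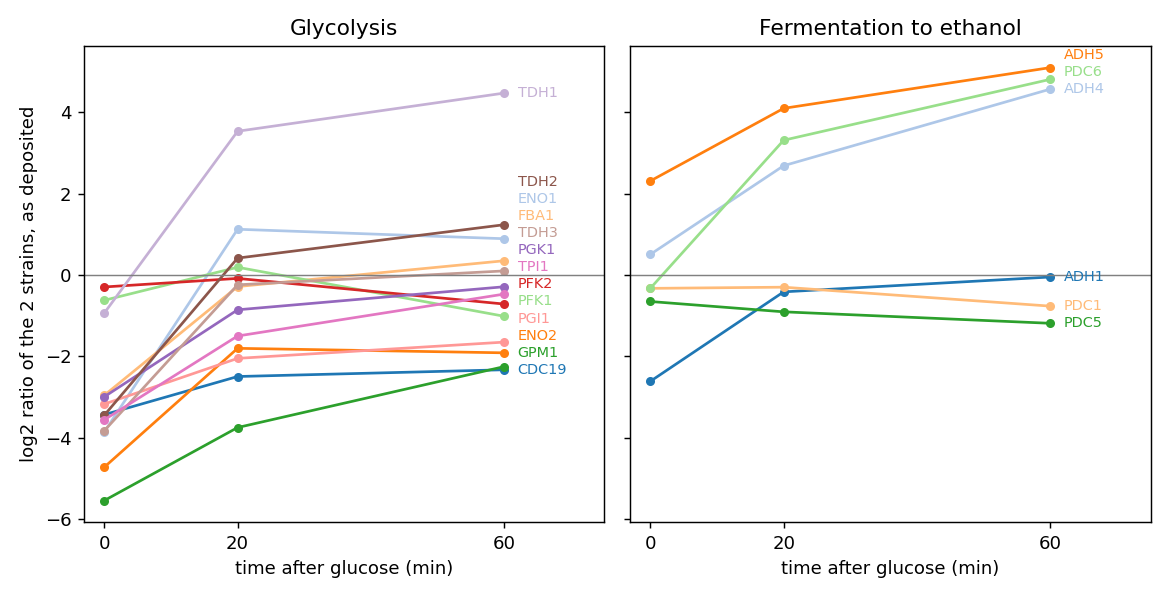
Log2 ratio of the 2 strains as deposited (vertical axis) against time after glucose in minutes (horizontal axis), 1 line per gene and 1 array per point, for 13 glycolytic genes (left) and 6 fermentation genes (right). Most glycolytic genes start between -5.55 and -2.96 at 0 min and lie nearer 0 at 20 and 60 min, whereas TDH1, ADH4, ADH5 and PDC6 lie above 2.6 at 20 min.

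Fermentation and sugar entry divided by gene after glucose. The 3 minor forms ADH5 (4.10), PDC6 (3.31) and ADH4 (2.69) were positive at 20 min and higher at 60 min, at 5.10, 4.81 and 4.57, while the main pyruvate decarboxylase PDC1 had -0.30 and -0.77 and ADH1 -0.41 and -0.05. PDC5 had -0.91 and -1.19. The list median of 1.19 at 20 min and 2.26 at 60 min thus rested on 3 of 6 genes. Of 17 genes for hexose transport and phosphorylation, 6 were at least 2-fold positive and 5 negative at 20 min (median 0.58), and 5 and 7 at 60 min (median -0.92). The positive members at 20 min included the glucose-phosphorylating enzymes GLK1 (4.18), HXK1 (2.67) and HXK2 (1.42). The high-affinity transporter HXT2 had 1.02 at 0 min, -2.82 at 20 min and -4.88 at 60 min, where it was the lowest gene on the array. HXT6 and HXT7, close copies of each other, had -2.25 and -2.15 at 20 min and -2.28 and -2.27 at 60 min.

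At 20 min the respiratory genes formed the most uniform positive group. All 16 measured genes of the TCA cycle were at least 2-fold positive, with a median of 3.01 (8.07-fold), led by citrate synthase CIT1 (5.32), the succinate dehydrogenase subunits SDH3 (4.19) and SDH1 (3.5) and the minor citrate synthase CIT3 (3.56). Of 34 nuclear genes of oxidative phosphorylation 33 were at least 2-fold positive, with a median of 2.28 (4.86-fold), among them QCR2 (4.26) and QCR6 (3.08) of complex III, ATP16 (3.11) of the ATP synthase and the internal NADH dehydrogenase NDI1 (3.14). The exception was the external NADH dehydrogenase NDE1 at -0.50. At 60 min the medians of these lists were 0.38 and 0.29, inside their random ranges, with 3 of 16 and 4 of 34 members at least 2-fold positive. Mitochondrial ribosomal proteins had medians of 0.09 at 20 min and 0.31 at 60 min, also inside the range.

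Genes for growth on non-fermentable carbon were positive at 20 min and less so at 60 min. At 20 min 16 of 20 were at least 2-fold positive, with a median of 2.03, including pyruvate carboxylase PYC1 (4.67), ALD4 (4.51), ADH2 (4.43) and the cytosolic isocitrate dehydrogenase IDP2 (3.32). At 60 min 9 of 20 were, with a median of 0.63, and PYC1 (4.59), ADH2 (2.77), the carnitine acetyltransferase YAT1 (2.42) and fructose-1,6-bisphosphatase FBP1 (2.28) were highest. ADY2 had -0.67 at 20 min and -1.09 at 60 min. A list of the pentose phosphate pathway that also held glycerol synthesis genes had a median of 1.5 at 20 min, with 9 of 13 members at least 2-fold positive and 2 negative, and 0.18 at 60 min. Its highest members at 20 min were the transketolase TKL2 (3.57) and the glycerol genes GPP2 (3.36) and GPD2 (3.13), and the aldehyde dehydrogenase ALD6 had -2.47. Storage carbohydrate genes had a median of 0.60 at 20 min, led by glycogen phosphorylase GPH1 (3.64) and phosphoglucomutase PGM2 (2.47), and -0.03 at 60 min.

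General stress genes were positive at both times after glucose. At 20 min 31 of 36 were at least 2-fold positive, with a median of 2.69 (6.46-fold), and at 60 min 24 of 36, with a median of 1.61 (3.06-fold), and 0 were 2-fold negative at either time. Catalase CTT1 (4.51 and 3.66), the chaperone HSP104 (4.49 and 2.70), the aldo-keto reductase GCY1 (4.48 and 3.12) and the membrane protein gene HSP12 (4.42 and 2.5) were among the highest at 20 min. At 60 min YGP1, a secreted glycoprotein gene, had 4.50 and the chaperone HSP42 3.77. Proteasome genes had a median of 0.61 at 20 min, with 31 of 32 above 0 and 8 at least 2-fold positive, and 0.18 at 60 min. RPN4, the activator of proteasome genes, was the member below 0 at 20 min, at -1.46.

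Genes for making ribosomes were most negative at 20 min, and the ribosomal proteins themselves at 60 min, though the list medians of both were negative at both times. Of 110 ribosome biogenesis genes 58 were at least 2-fold negative at 20 min (median -1.01) and 25 at 60 min (median -0.69), led by SDA1 (-2.45) and UTP22 (-2.23) at 20 min. At 0 min their median was 0.05, and -0.02 after centring. Of 20 subunits and factors of RNA polymerases I and III, 15 were at least 2-fold negative at 20 min (median -1.36) and 5 at 60 min (median -0.73), and the polymerase I initiation factor RRN3 was lowest at -3.29 at 20 min. The cytosolic ribosomal proteins had a median of -0.56 at 20 min, outside the random range, with 122 of 135 below 0 and 14 at least 2-fold negative. At 60 min their median was -2.07 (4.20-fold), with 127 of 135 at least 2-fold negative. Lowest at 60 min were RPL9A (-3.65), RPL14A (-3.28), RPL14B (-3.06) and RPL9B (-2.91). Translation factors had medians of -0.34 and -0.55, and the latter was outside the random range with 0 of 28 beyond 2-fold.

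**Figure D3:**
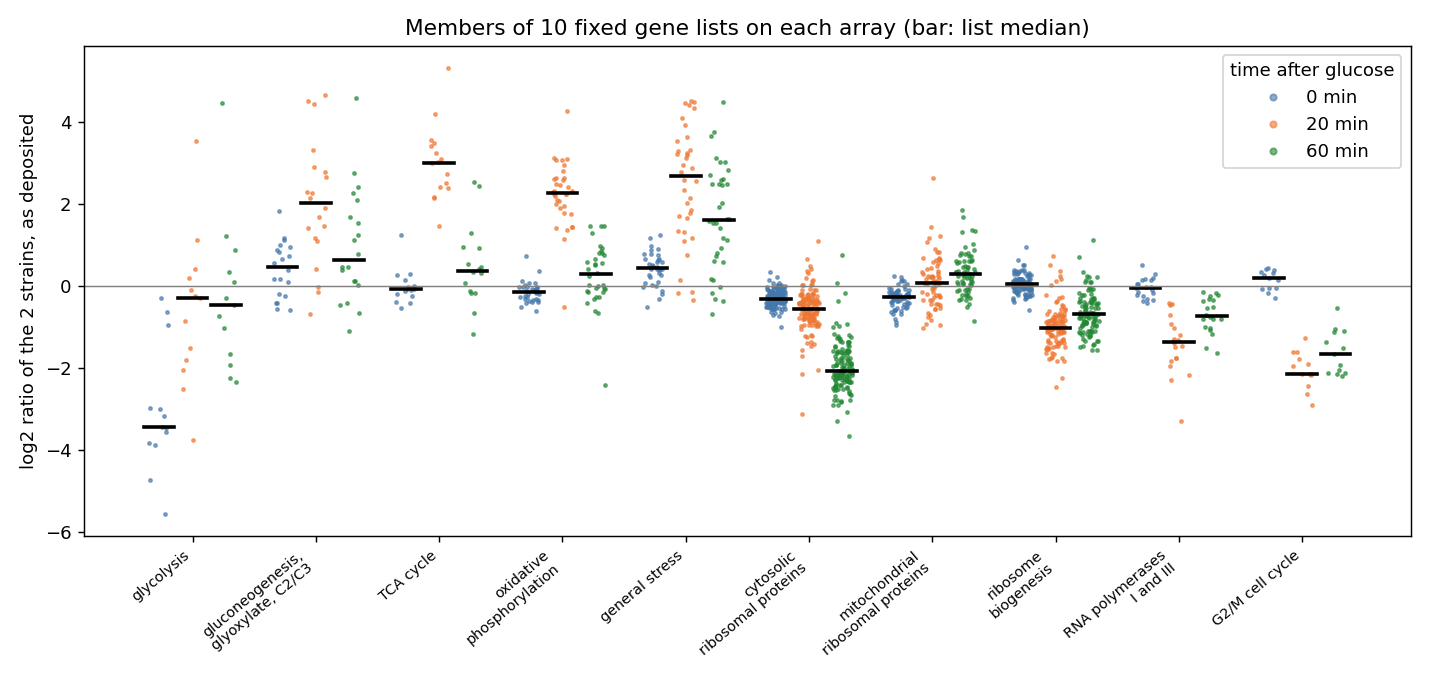
Log2 ratio of the 2 strains as deposited (vertical axis) for each member of 10 gene lists (horizontal axis) on the arrays at 0, 20 and 60 min, 1 point per gene and 1 array per time, with a bar at the list median. At 20 min the TCA cycle, stress and oxidative phosphorylation lists have medians of 3.01, 2.69 and 2.28, and at 60 min the cytosolic ribosomal proteins have a median of -2.07.

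Cell cycle genes were also on the negative side after glucose. All 13 genes of the G2/M list were at least 2-fold negative at 20 min, with a median of -2.13 (4.38-fold), and 12 of 13 at 60 min, with a median of -1.65, among them the transcription factor SWI5 (-2.89 and -2.14), the mitotic activator CDC20 (-2.64 and -1.92) and the cyclin CLB1 (-1.95 and -2.12). M/G1 genes had medians of -0.84 at 20 min and -1.10 at 60 min, with 9 and 12 of 19 at least 2-fold negative. The replication helicase gene MCM7 had -2.07 and -1.90, and the cell separation gene DSE4 -1.87 and -3.14. G1/S genes had -0.09 at 20 min, inside the range, and -0.77 at 60 min, with 10 of 26 at least 2-fold negative, including the polymerase clamp POL30 (-2.16) and the cyclin CLN2 (-1.94). Histone genes were inside the range at 20 and 60 min, at 0.07 and -0.06.

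Amino acid, sulfur and nucleotide genes differed member by member. Of 46 amino acid biosynthesis genes 20 were at least 2-fold positive at 20 min (median 0.87), led after GCN4 (7.83) by LEU2 (3.71) and the homocitrate synthase LYS20 (3.65), while the serine synthesis gene SER3 had -3.22. At 60 min GCN4 stood at 7.40 and the list median at 0.18, inside the range. Sulfur and methionine genes had medians of 0.16, 0.32 and 0.91, outside the range at 60 min, where 11 of 24 were at least 2-fold positive and 5 negative, with the regulator MET28 at 3.34 and the transporter SAM3 at 3.16 but S-adenosylmethionine synthetase SAM1 at -3.01. Purine genes had medians of -0.61 at 20 min and 0.35 at 60 min, and the synthesis gene ADE17 had -2.79 and 2.23. Ergosterol genes had 0.19, -0.16 and -0.48, outside the range at 60 min with 8 of 23 at least 2-fold negative, led by the desaturase ERG3 (-2.37).

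Several single genes ranked among the 8 highest or lowest after glucose. At 20 min GPM2, a relative of GPM1, had 5.50, the CoA transferase ACH1 5.38, the lactate dehydrogenase DLD3 5.37, the peroxisomal citrate synthase CIT2 5.04, UGA2 of GABA breakdown 5.01 and the polyamine oxidase FMS1 4.87. The pheromone gene MF(ALPHA)2 was lowest at -4.22, followed by GPM1, the importin KAP122 (-3.69), SFG1 (-3.52), FAR1 (-3.48), RRN3, the RNA cleavage factor RNA14 (-3.24) and the tRNA exporter LOS1 (-3.23). At 60 min GPM2 reached 7.35, a 163-fold difference, and FMS1 had 6.11, DLD3 5.63, YRO2 5.04 and GPG1 4.93. The phosphate transporter PHO84 (-4.57), the phosphatase PHO3 (-4.16), SPL2 (-3.82), MF(ALPHA)2 (-3.78) and MGA1 (-3.75) were among the lowest. The phosphate list as a whole had medians of 0.04, -0.45 and -0.29, inside the range, and its 0 min value was -0.03 after centring.

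The remaining lists included checks of strain background and other cell states. Mating and pheromone genes had medians of -0.48, -1.29 and -0.49, outside the range on all 3 arrays, with 1, 11 and 5 of 19 at least 2-fold negative, and the receptor genes of both mating types, STE2 (-1.93) and STE3 (-2.21), were negative at 20 min. PRM1, a gene of cell fusion, was positive at 2.5 at 20 min and 3.47 at 60 min. The 8 laboratory marker genes had medians of 0.22, -0.03 and 0.90, outside the range at 60 min, and the 20 min value was 0.05 after centring. URA3 had 2.83, 2.07 and 2.39, LEU2 0.69, 3.71 and 2.82, and HIS3 -1.65, -1.27 and -1.44, with HIS3 at low signal on all 3 arrays. Genes for sucrose, maltose and galactose use had 0.05, -0.45 and -0.65, outside the range at 60 min, where the regulator MTH1 was lowest at -3.06, and the 0 min value was -0.02 after centring. Secretory pathway genes had 0.05, -0.01 and -0.50, outside the range at 60 min, and the values at 0 and 20 min were -0.02 and 0.07 after centring. Iron genes (0.07, -0.18 and 0.35, with -0.01 at 0 min after centring), hypoxic genes (-0.11, -0.30 and -0.20) and sporulation genes (-0.04, -0.08 and 0.51) were inside the range on all 3 arrays. In all, 13 of 32 lists were outside their range at 0 min, 17 at 20 min and 17 at 60 min.

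Differences between the arrays give the strain ratio in glucose relative to that on pyruvate. Each equals the numerator strain's change with time minus the other strain's, so it does not tell which strain changed. The ratio was at least 2-fold higher at 20 min than at 0 min for 902 genes and lower for 916. That split was 1068 to 712 after centring, which shifted these differences by 0.15, and 1083 to 704 after scaling to equal spread. CIT1 (5.16), ACH1 (5.03), ENO1 (4.99), the chaperone SSA1 (4.75), GPM2 (4.69), PHM8 (4.61), SDH3 (4.57) and UGA2 (4.55) had the largest positive differences. SER3 (-3.86), HXT2 (-3.84), RRN3 (-3.81), KAP122 (-3.63), RNA14 (-3.48), the uridine transporter FUI1 (-3.45), MF(ALPHA)2 (-3.31) and FAR1 (-3.24) had the largest negative ones. By list, the median difference was 2.14 for glycolysis, with 10 of 13 members higher by at least 2-fold, 2.92 for the TCA cycle, 2.47 for oxidative phosphorylation and 2.27 for stress genes, and -2.35 for G2/M genes, -1.17 for RNA polymerases I and III and -1.01 for ribosome biogenesis. Under scaling to equal spread, glycolysis had 7.17, stress genes 0.88, the polymerases -0.47 and ribosome biogenesis -0.67. The cytosolic ribosomal proteins had -0.24, inside the range, and 0.48 under that scaling.

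Between 0 and 60 min the ratio was at least 2-fold higher at the later time for 862 genes and lower for 746. GPM2 (6.54), TDH1 (5.41), PDC6 (5.14, with low signal at 0 min), FMS1 (5.14), YRO2 (4.80), ENO1 (4.75), GPG1 (4.71) and TDH2 (4.69) had the largest positive differences, and HXT2 (-5.89), PHO84 (-5.15), PHO3 (-4.67), RPL9A (-3.41), SPL2 (-3.32), ALD6 (-3.24), MGA1 (-3.18) and DSE4 (-3.12) the largest negative ones. The glycolysis median was 3.09 (7.57 under scaling to equal spread), with 11 of 13 members higher by at least 2-fold, and that of the cytosolic ribosomal proteins was -1.73 (-0.81 under that scaling), with 119 of 135 lower by at least 2-fold.

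Between 20 and 60 min the respiratory genes and the ribosomal proteins had negative differences. The ratio was at least 2-fold higher at 60 min for 473 genes and lower for 569. That split was 330 to 674 after centring, which shifted these differences by -0.13, and 141 to 443 after scaling to equal spread. All 16 TCA cycle genes and 31 of 34 oxidative phosphorylation genes were lower by at least 2-fold, with medians of -2.44 and -1.90, led by SDH3 (-3.88), QCR2 (-3.60) and SDH1 (-3.42). Fatty acid oxidation genes FAA2 (-3.88), FOX2 (-3.40) and POT1 (-3.31), together with MDG1 (-3.72) and KGD4 (-3.35), completed the 8 lowest. The cytosolic ribosomal proteins had a median of -1.51 with 109 of 135 lower by at least 2-fold, while ribosome biogenesis had 0.39 (0.15 under scaling to equal spread). ADE17 (5.02), FUI1 (3.73), PRM5 (2.81), SER3 (2.78), ACA1 (2.72), the uracil permease FUR4 (2.65), YPL088W (2.46) and ADE1 (2.34) had the largest positive differences.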

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

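All tests of technical explanations in this part were chosen after the results were seen, and differences between time points were not tested, since each rests on 1 array per time.

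Some groups and genes lay on opposite sides at different times, which is why they are listed. The fermentation list had medians of -0.33 at 0 min, 1.19 at 20 min and 2.26 at 60 min. Hexose transport and phosphorylation had 0.58 at 20 min and -0.92 at 60 min. Oxidative phosphorylation had -0.15 at 0 min and 2.28 at 20 min, purine biosynthesis 0.29 at 0 min and -0.61 at 20 min, and G1/S genes 0.30 at 0 min and -0.77 at 60 min. Among single genes, ENO1 had -3.86 at 0 min and 1.12 at 20 min, and TDH2 had -3.45 at 0 min and 1.24 at 60 min. HXT2 had 1.02, -2.82 and -4.88 at 0, 20 and 60 min, and PDR12 had 1.66, 1.01 and -1.04. ADY2 had 1.83 at 0 min and -1.09 at 60 min, and ADE17 had -2.79 at 20 min and 2.23 at 60 min.

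The probes without a gene name were not used in any comparison. Of 1605 such probes, 140 had a log2 ratio of -6 or lower on all 3 arrays, and 0 of the named probes did.

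The respiratory genes, TCA cycle and oxidative phosphorylation together, were positive at 20 min while close to 0 at 0 min. Of the 50 genes, 0 were of low signal at 20 min. That cannot decide on spots of low signal, because the rule cannot flag ratios beyond 8-fold after the array's offset. The TCA cycle median alone was 3.01 (8.07-fold), so spots of low signal stay open. A constant dye or probe bias would cancel in the difference between arrays, where the median was 2.54 (95% bootstrap interval over genes 2.38 to 2.79). Ribosomal protein and elongation factor genes, used as other abundant transcripts, stood at -0.54 (-0.61 to -0.41). They cannot decide on a bias towards abundant transcripts, because the ribosomal proteins were themselves outside their random range on all 3 arrays. Array intensities were not analysed either, so such a bias stays open. Also open are a bias of the 20 min array alone and variation between single cultures, which 1 array per time point leaves untested. A difference between the strains in the response to glucose also stays open and was not tested.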

How the results depend on the processing

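The alternative that left out genes of low signal was chosen after the data were seen. No paired analysis within a time point was possible, because each time point had 1 array, and so 1 pair of strains. A strain effect common to the 3 arrays, each of which pairs the strains, was not tested. No list median changed sign where the list was outside its random range; some medians inside the range did. Under scaling to equal spread, the difference 20 minus 0 min went from -0.49 to 0.94 for mating genes, from -0.24 to 0.48 for cytosolic ribosomal proteins, from 0.13 to -0.17 for storage carbohydrate genes and from -0.10 to 0.38 for marker genes, and the gluconeogenesis difference 60 minus 0 min went from 0.27 to -0.12. Other medians that changed sign ran from -0.10 to 0.07 before and after those settings. Signal over background was not analysed here, so the limit of dim spots is known only through the low-signal values.

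At 1.5-fold the positive counts were 299, 1487 and 1585 and the negative counts 296, 1623 and 1371 at 0, 20 and 60 min, and at 3-fold they were 9, 497 and 426 and 64, 320 and 296, as a looser or stricter threshold must give. For differences 20 minus 0, 60 minus 0 and 60 minus 20 min, 1.5-fold gave 1433, 1514 and 1399 genes with a higher strain ratio at the later time. Those with a lower ratio numbered 1643, 1418 and 1056. Leaving out genes of low signal gave 29 negative genes at 0 min, and the cause was not tested. Scaling the arrays to equal spread widens the 0 min array and narrows the others by construction. It gave 471 positive and 672 negative genes at 0 min, 458 negative genes at 20 min and 595 positive genes at 60 min. The strain ratio was at least 2-fold higher at 60 than at 20 min for 141 genes. Without genes beyond 2-fold on either array, the correlation was 0.157 for 0 and 20 min, 0.116 for 0 and 60 min and 0.432 for 20 and 60 min, a narrower range of values by construction.

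Under the same scaling, list medians at 0 min were -8.47 for glycolysis, 0.98 for gluconeogenesis, -0.34 for the TCA cycle, -0.53 for oxidative phosphorylation, -0.91 for cytosolic ribosomal proteins, -0.052 for ribosome biogenesis, -0.26 for RNA polymerases I and III and 0.91 for stress genes. At 20 min they were 2.32 for the TCA cycle, 1.77 for oxidative phosphorylation, -0.36 for ribosomal proteins, -0.70 for ribosome biogenesis and -0.96 for the polymerases, and at 60 min -1.69 for ribosomal proteins and -0.59 for ribosome biogenesis. Differences 20 minus 0 min became 7.17 for glycolysis, 0.48 for ribosomal proteins, -0.67 for ribosome biogenesis, -0.47 for the polymerases and 0.88 for stress genes. Those for 60 minus 0 min became 7.57 for glycolysis, 0.81 for oxidative phosphorylation, -0.81 for ribosomal proteins, -0.51 for ribosome biogenesis, -0.32 for the polymerases and 0.37 for stress genes. Those for 60 minus 20 min became -1.92 for the TCA cycle, -1.51 for oxidative phosphorylation, -1.31 for ribosomal proteins, 0.15 for ribosome biogenesis and 0.35 for the polymerases. Centring each array gave -0.38 for ribosomal proteins and -0.021 for ribosome biogenesis at 0 min, since it subtracts the array median. For differences it gave -0.09 and -1.63 for ribosomal proteins and -0.86 and 0.26 for ribosome biogenesis, 20 minus 0 and 60 minus 20 min. The totals that follow count comparisons of 1 value with 1 alternative, so the same value recurs under several alternatives. For the 10 main lists, 163 other comparisons of a list median stayed within the bootstrap interval of its members. For differences or their counts, 87 comparisons stayed within that interval or within 1.5 times. For the remaining lists 379 comparisons of medians and 185 of differences did so, and 17 and 13 did not. Among the other values, 31 comparisons of gene counts stayed within 1.5 times, 9 of correlations within 0.1 and the 3 GCR1 values within the probe error. Under scaling to equal spread, 36 comparisons of main results moved and 36 stayed.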

Other observations

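All tests, gene pairs and added lists in this part were chosen after the values were seen.

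For most glycolytic and fermentative enzyme pairs compared, a related gene had a higher ratio than the main form. Of 15 pairs, this held for 13 at 0 min and 14 at both 20 and 60 min, by at least 2-fold for 9, 12 and 12. The pairs share 7 main forms and are not independent, and 6 of those beyond 2-fold on each array were set against ADH1 or GPM1. Main forms such as GPM1 (-5.55), CDC19 (-3.43) and ADH1 (-2.61) were themselves strongly negative at 0 min. Any gene near 0 exceeds these, as did GPM3 (-0.15), PYK2 (0.12) and ADH3 (-0.02) there. How often unrelated genes would do so was not computed, so the counts do not show a pattern particular to related enzymes. GPM2 exceeded its relative GPM1 by 6.35, 9.25 and 9.60. ADH5 exceeded ADH1 by 4.92, 4.51 and 5.15. PYK2, the minor pyruvate kinase, exceeded CDC19 by 3.55, 3.74 and 3.08, and CDC19 matched the low-signal rule at 60 min. PDC6 equalled PDC1 at 0 min and exceeded it by 3.61 and 5.58 later, with PDC6 at low signal at 0 min. PDC5 was lower than PDC1 on all 3 arrays, at -0.32, -0.61 and -0.42 relative to PDC1.

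Fatty acid oxidation and peroxisomal genes had medians of 0.78 at 0 min, 1.40 at 20 min and 0.21 at 60 min over 16 genes, with 4, 9 and 4 at least 2-fold positive. FOX2, the multifunctional enzyme of beta-oxidation, had 0.51, 4.81 and 1.41, and the thiolase POT1 had 1.10, 3.59 and 0.29. Genes for pyrimidine synthesis and uracil uptake had medians of 0.46, -0.15 and 1.20 over 11 genes, with 1 positive and 0 negative by at least 2-fold at 0 min, 3 and 3 at 20 min and 6 and 3 at 60 min. Negative at 60 min were URA1 (-1.79), URA7 (-1.66) and URA5 (-1.6). Among the others, FUI1 had 0.92, -2.54 and 1.20, FUR4 0.49, -0.14 and 2.51 and URA10, at low signal at 0 min, 2.05 at 20 min and 3.52 at 60 min.

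GCN4 was the highest gene on all 3 arrays, at 7.66, 7.83 and 7.40. Its ratio ranged by 0.43 over the arrays, but a weak channel at its floor or a saturated one would also hold so large a ratio steady, so a fixed difference between the strains at this locus stays open. The amino acid biosynthesis genes without GCN4 did not differ to that extent. Their median was 0.29 at 0 min (95% bootstrap interval over genes 0.22 to 0.35) and 0.11 at 60 min (-0.37 to 0.68). Both intervals lay below the limit of 1 set for this check after the values were seen. At 20 min their median was 0.86 (0.20 to 1.30), where GCN4 had 7.83. That interval passed the limit, so the check cannot decide there. How these transcripts follow the activity of the Gcn4 protein was not measured, so a difference in activity stays open on all 3 arrays. No other explanation of the GCN4 ratio was tested.

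GCR1 was positive on all 3 arrays, with a largest value of 1.51 (its probes over the arrays 0.90 to 1.53). Whether the probed sequence was absent from 1 strain stays open, because the value an absent sequence gives on these arrays was not measured. The values alone do not name the numerator, because the sign of every ratio would turn together. At 0 min all 13 glycolytic genes were negative, with a median of -3.43, on the side opposite to GCR1. Because GCR1 encodes an activator of glycolytic genes, these values argue against wild type over mutant. The positive GCR1 ratio goes the other way if its probes lie in the deleted part, so signs stay given as positive or negative. Partial deletion with probes outside it remains a possible explanation of the GCR1 values that was not tested.

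Genes at least 4-fold to the same side on all 3 arrays were ADH5, GCN4, IMD2 and URA3 on the positive side. On the negative side they were CDC19, GPM1, YCL042W and YIR042C. YCL042W and, at 60 min, CDC19 matched the low-signal rule. YIR042C had -2.77, -2.23 and -2.27. Medians over the genes of each of 16 chromosomes ran from -0.11 to 0.12 at 0 min, -0.24 to 0.01 at 20 min and -0.16 to 0.22 at 60 min.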
